A study of Mus musculus with 3 samples.

How the data were processed

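RNA was measured in 3 samples of mouse plasmacytoid dendritic cells grown from bone marrow, 1 array per group, with a whole-transcript expression array that reports each transcript as a probe set. Per the labels, total RNA was made into biotin-labelled cRNA with a whole-transcript kit, and each sample was hybridised to 1 array. The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA subtracts background, equalises the arrays by quantiles and summarises the probes of a probe set by median polish. The software, its version and the variant of RMA are not given in the sources used here. The log base was read from the range of the values, 1.78 to 19.7, and from RMA's usual output. The values were neither centred per gene nor ratios, so no direction was left open.

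The median over all 28846 probe sets was 5.68 in the control array, 5.74 in the astragaloside IV array and 5.75 in the oxymatrine array. Median polish over 3 arrays gives many values that are exactly equal: 56.0% of the named probe sets had the same value in at least 2 arrays, which is why medians of gene lists often came out at 0. Arrays have no read depth, and their number limits the precision here.

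Probe sets were named through the platform's annotation, dated 2019, in which 19572 had 1 gene symbol, 0 had several and 9274 had none. All 19572 Entrez identifiers were found in a current RefSeq gene table, and 0 symbols differed. No genome build is named for the array design in the sources used here, so no coordinates are given. For the 55 genes with several probe sets, the one with the highest mean over the 3 arrays was used, which left 19505 genes. The main set held the 10671 genes whose mean over the 3 arrays reached the 95th percentile of 1410 olfactory and vomeronasal receptor genes, a log2 level of 5.28. Those receptor genes are normally silent in blood cells and served as the reference for dim probe sets.

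Each comparison is the difference of 2 deposited log2 values. With 1 array in each group there are no replicates, so no test, p-value or standard error was computed for any gene, and genes were counted by size, at 2-fold or more. Beside single genes stands the SD of the same difference over genes of similar level, from 20 bins of equal size. It describes how far genes of that brightness lay apart and is not a replicate error. For 35 gene lists, each list median was placed among 10000 random lists of the same size, matched on level in the 20 bins, where at least 5 members were above background. A percentile outside 2.5 to 97.5 describes these arrays and does not test the conditions. For the values that share the control array, each gene's 3 values were shuffled among the arrays 100 times.

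The comparisons, gene lists, thresholds and the rule for naming genes were fixed before the data were examined. The rule took the 12 genes highest and the 12 lowest in each treated array against control, 6 each way between the treated arrays, the overlap, up to 4 members of each list and a fixed set of migration and identity genes. Some items, among them 1 of the gene lists, are not reported here. Predicted genes, numbered clones, receptor genes and small RNAs were counted and not named. Alternatives were another level filter or none, thresholds of 1.5-fold and 3-fold, centring on the median, quantile normalisation, lowess centring (fraction 0.3), averaging over probe sets, the list mean and all measured members. The 3 following choices were made after the data had been seen: random lists drawn from the listed genes, a ranking by the SD at a gene's level, and a stricter match of listed symbols. A listed symbol was at first matched through any synonym, which put 4 genes other than those meant (Tom1l2, Pigq, Eno1b and Cd300c2) into lists. The rule was then limited to symbols that name no current gene, and the first rule was kept as an alternative.

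The calculations were tested on simulated data with the level and spread of the astragaloside IV and control arrays over 10671 genes. In that simulation 100 of 100 genes moved 3-fold and 3 of 100 moved 1.5-fold passed the 2-fold threshold, as did 0 of 10471 unmoved genes. The simulated noise followed a normal distribution, while 27.7% of the real differences between these 2 arrays were exactly 0. The 0 unmoved genes therefore do not give the rate at which noise passes 2-fold in the real arrays. A list moved by 0.10 on the log2 scale went from the percentile 33.8 to 99.96, and 3 of 100 random lists fell outside the central 95%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.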

Results

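Plasmacytoid dendritic cells, the dendritic cells that make large amounts of type I interferon, were grown from the bone marrow of male BALB/c mice aged 4 to 5 weeks. The marrow was cultured with Flt3 ligand at 100 ng/mL for 6 to 9 days, matured with CpG oligodeoxynucleotides, which are ligands of TLR9, and sorted. One array was run on control cells, 1 on cells given astragaloside IV, a saponin of Astragalus root, and 1 on cells given oxymatrine, an alkaloid of Sophora root. Both compounds were present for 12 h, and CCL21, a ligand of the chemokine receptor CCR7, was then added for 1 h. The study asked how both compounds inhibit the migration of these cells. The doses are not stated, nor whether the control cells received CCL21 or a vehicle, so a difference from control cannot be assigned to a compound apart from the CCL21 step. There were no replicates, and every value is that of a single array.

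The 3 arrays were close to one another. Across the 19572 named probe sets, Pearson's r was 0.998 between astragaloside IV and control, 0.997 between oxymatrine and control and 0.998 between the treated arrays. Exonic control probe sets outranked intronic ones in each array, with an area under the curve of 0.868 in control, 0.854 with astragaloside IV and 0.848 with oxymatrine. The cells carried transcripts of the plasmacytoid dendritic cell lineage in all 3 arrays. Tcf4, the transcription factor that maintains this lineage, was at a log2 level of 14.37 in each array, and Bst2 was at 12.09 in control, 12.09 with astragaloside IV and 12.08 with oxymatrine. Siglech, a surface marker of the lineage, was at 8.99, 8.99 and 9.02 in the same order, and Tlr9 at 12.62, 12.53 and 12.62. Irf7, the main inducer of interferon alpha genes, was at 15.05 in control, 14.95 with astragaloside IV and 14.84 with oxymatrine. Of 22 plasmacytoid dendritic cell markers above background, 11 were lower, 3 higher and 8 equal with astragaloside IV, and 12 were lower, 5 higher and 5 equal with oxymatrine, with none 2-fold apart. Those 22 were out of 26 measured. Of conventional dendritic cell markers, 10 of 13 for type 1 and 11 of 14 for type 2 were above background. All 18 measured markers of monocytes and macrophages were above background as well, so detection alone does not set the lineage apart.

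Of the receptors that guide these cells, Ccr7, the receptor for CCL21, was at 16.32 in control, 16.35 with astragaloside IV and 16.26 with oxymatrine. Cxcr4 was at 13.58, 13.60 and 13.48 in the same order, Ccr2 at 10.43, 10.43 and 10.28, and Ccr9, the receptor that directs these cells to the gut, at 9.46, 9.20 and 9.15. Cxcr3 was at 6.18 in each array, Cmklr1 at 7.49, 7.24 and 7.49, S1pr4 at 6.79, 6.72 and 6.83, and Itgb7 at 9.42, 9.36 and 9.50. Ccl21a, a gene for the added chemokine itself, was near background at 5.54, 5.69 and 5.93. Ccr3 differed from control by -0.81 with astragaloside IV and -0.57 with oxymatrine, Ccr4 by -0.09 and -0.72, and Ccr6 by -0.33 and -0.51. Of 20 chemoattractant receptors above background, 12 were lower and 4 higher with astragaloside IV, with a median of -0.06 at the percentile 1.96 of level-matched random lists. This lay inside the central 95% under 2 other level filters and with all measured members, and the median was -0.04 after centring on the median and -0.10 after quantile normalisation. With oxymatrine 13 were lower and 2 higher, with a median of -0.08 at the percentile 3.21, inside the central 95%, and a mean at the percentile 0.87, outside it.

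Among cytoskeletal genes lower values were more frequent than higher ones, and none of these genes reached a 2-fold difference. Of 70 genes of actin polymerisation and actomyosin, 30 were lower, 15 higher and 25 equal with astragaloside IV, and 28 were lower, 16 higher and 26 equal with oxymatrine. The actin cross-linker Flna was higher with oxymatrine by 0.42, while Mylk, the myosin light chain kinase gene, differed by -0.62 and the formin gene Fmnl1 by -0.33. Among 35 integrins and adhesion molecules, Cd99 differed by -0.48 with astragaloside IV and -0.69 with oxymatrine, and Itgae by -0.73 and -0.49. The median difference was 0 for both of these lists in both comparisons with control, at percentiles between 57.5 and 77.2 of level-matched random lists. The upper edge of the central range of random medians was itself 0, so these percentiles do not place the lists above the middle. By their means, the actin and actomyosin genes lay at the percentile 21.9 with astragaloside IV and 41.1 with oxymatrine. The integrins and adhesion molecules lay at 22.3 and 51.8 in the same order.

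**Figure D1:**
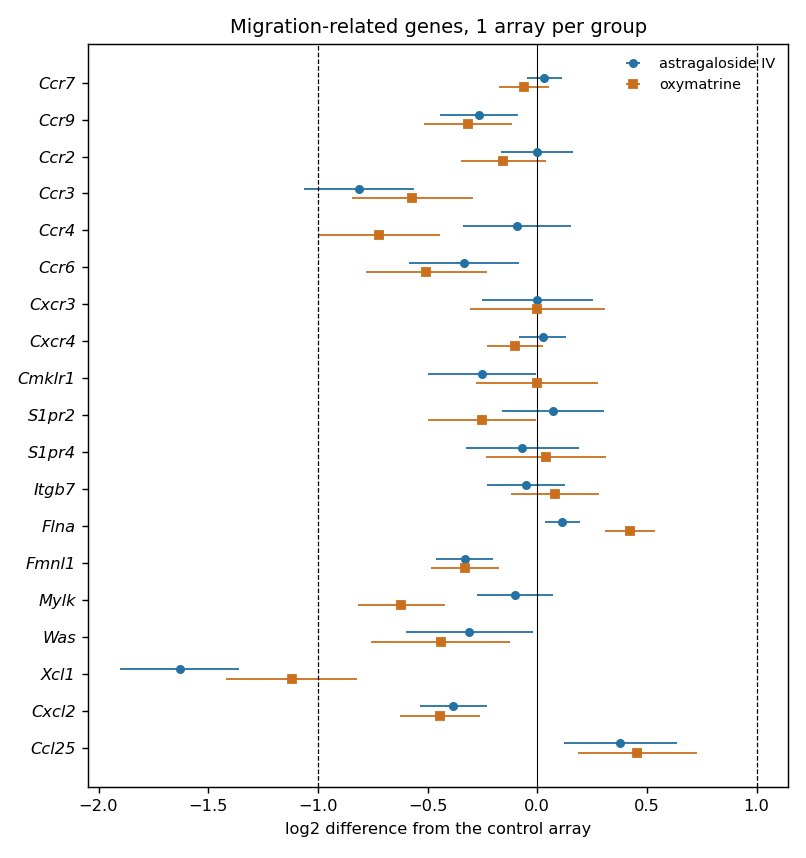
Log2 difference of the astragaloside IV array (circles) and the oxymatrine array (squares) from the control array for chemoattractant receptors, Itgb7, cytoskeletal genes and chemokines, with bars of 1 SD of the same difference over genes of similar level and dashed lines at 2-fold. Ccr7 and Cxcr4 lie near 0, Xcl1 lies past 2-fold in both treated arrays at -1.63, from a value below background, and -1.12, and the other genes lie within 2-fold.

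In the astragaloside IV array Wfdc9 was lower than control with a log2 difference of -1.58, Tecpr2 with -1.34, Myo9a, an unconventional myosin, with -1.31 and Fkbp1b with -1.10. Xcl1, which encodes the chemokine lymphotactin, differed by -1.63, Sh2b1, an adaptor of receptor tyrosine kinases, by -1.37, Qpct by -1.28, Abl1 by -1.21, the gap junction gene Gja1 by -1.14 and the desaturase gene Scd3 by -1.07. These 6 lay below the background level of 5.28 in the treated array, so their sizes and ranks rest on a value that is not above background. On the higher side stood Zfp763 with 1.12, Ypel1 with 1.04 and Zfp987 with 1.00, and Zg16 with 1.25 from a control value below background. In all, 21 of 10671 genes, or 0.197%, were 2-fold apart, 4 higher and 17 lower in the treated array, 14 of them above background in both arrays. With no level filter 42 were higher and 37 lower.

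Most of these genes were dim. The median level of the 21 genes was 6.33, and Ypel1 was the only 1 with a mean level of 9 or more, with 9.01 in control and 10.05 in the treated array, 6.04 times the SD of genes of its level. Xcl1 lay at 6.66 in control and 5.03 in the treated array, a difference of -6.03 times that SD. Of the 1410 olfactory and vomeronasal receptor genes, 19, or 1.35% (95% exact binomial interval 0.813 to 2.10%), were 2-fold apart in the same comparison, all of them below the background level, as 0 of the 71 above it were. At 1.5-fold, 90 genes were higher and 137 lower.

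Chemokine genes lay low as a group in the astragaloside IV array. Of 21 chemokine genes above background, 15 were lower, 4 higher and 2 equal, and their median difference of -0.10 stood at the percentile 0.1 of random lists. Cxcl2, a neutrophil-attracting chemokine, differed by -0.38, while Ccl25, the ligand of Ccr9, was higher by 0.38 and the interferon-induced Cxcl11 by 0.29. Genes of the unfolded protein and integrated stress response were lower in 20 of 30 cases and higher in 4, with a median of -0.08 at the percentile 0.03. Edem1, which helps to dispose of misfolded glycoproteins, differed by -0.38, Chac1 by -0.35 and the amino acid transporter gene Slc7a5 by -0.28. Beside both groups, 3 of 19 measured neutrophil markers were above background, and these were lower in this array, Lcn2 by a difference of -0.51, Csf3r by -0.49 and Mmp8 by -0.26. Of 6 T and NK cell markers above background, Il2rb differed by -1.01 and Cd5 by -0.45, while the other 4 were equal to control. The median of these markers was 0, at the percentile 58.5. Exonic control probe sets were lower in this array by a mean of -0.04 and intronic ones higher by 0.16.

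In the astragaloside IV array, targets of liver X receptors and fatty acid synthesis genes were lower in 15 of 16 cases, with a median of -0.08 at the percentile 1.34. The exception was Acaca, which encodes acetyl-CoA carboxylase and was higher by 0.61, whereas the cholesterol exporter gene Abca1 differed by -0.28 and Scd1 by -0.30. Endosomal toll-like receptor signalling genes had a median of -0.06 with 15 of 25 lower, and oxidative stress response genes a median of -0.04 with 17 of 27 lower, among them Osgin1 at -0.70 and Gclc at -0.38. After centring on the median, the medians of the last 2 lists were -0.04 and -0.01. Without centring, the mean of the oxidative stress list was -0.08. By their means, the liver X receptor list lay at the percentile 13.1 and the toll-like receptor list at 22.75, inside the central 95%. The oxidative stress list was inside with all measured members and with no level filter, and the liver X receptor list with the 99th percentile filter. With chemokine, unfolded protein and chemoattractant receptor genes, 6 lists were outside the central 95% of random lists, out of 31 placed. For lists of unrelated genes 1.55 would be outside. Members of a list can move together and lists share genes, so 1.55 does not measure chance for these lists. Listed genes lay low in general, with the means of 27 of 31 lists below the middle of level-matched random lists. A mean below 0, found in 30 of 31, says less, since the mean over all 10671 genes was -0.02. With random lists drawn from the listed genes only the chemokine and the unfolded protein lists stayed outside, at the percentiles 0.825 and 1.18.

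In the oxymatrine array the 2-fold differences went both ways. Among genes above background in both arrays, Nuak2, an AMPK-related kinase, and Spice1 differed by -1.19 each, Pex5, the import receptor of peroxisomes, by -1.16, Hvcn1, a proton channel of immune cells, by -1.15, Map4k5 by -1.13 and Xcl1 by -1.12. Scd3 differed by -1.23, the tyrosine kinase gene Abl1 by -1.21 and Rundc3b by -1.21, all with a treated value below background. Higher were the beta-defensin gene Defb46 with 1.54, Gsdma2 with 1.39, Smim5 and Tph2, which encodes neuronal tryptophan hydroxylase, with 1.32 each, and Tcl1b4 with 1.26 from a control value below background. In all, 30 of 10671 genes, or 0.281%, were 2-fold apart, 14 higher and 16 lower, 19 of them above background in both arrays. After quantile normalisation 10 were higher and 24 lower, and with no level filter 57 were higher and 33 lower.

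Nuak2 stood out among bright genes, at 12.25 in control, 12.06 with astragaloside IV and 11.06 with oxymatrine, where it differed from control by -7.39 times the SD of genes of its level. Map4k5 differed by -5.78 times that SD, at 10.86 in control and 9.73 with oxymatrine, and Ypel1 by 5.47 times, at 9.01 and 10.08. These 3 were the only ones of the 30 at a mean level of 9 or more, and the median level of the 30 was 5.99. Of the 1410 receptor genes, 15, or 1.06% (95% exact binomial interval 0.597 to 1.75%), were 2-fold apart, and 0 of the 71 above the background level were. At 1.5-fold, 139 genes were higher and 214 lower.

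Cell cycle and respiratory chain genes lay low in the oxymatrine array, though not there alone. With astragaloside IV, 23 cell cycle genes were lower and 7 higher, and 22 oxidative phosphorylation genes were lower and 6 higher. Their medians there were -0.03 and -0.02, at the percentiles 4.64 and 5.62, inside the central 95%. Of 38 cell cycle genes, 26 were lower and 9 higher, with a median of -0.10 at the percentile 0.65, and the spindle genes Prc1 and Tpx2 differed by -0.88 and -0.40 and the mitotic kinase gene Aurkb by -0.54, while Cdc6 was higher by 0.63. Of 36 oxidative phosphorylation genes, 23 were lower and 8 higher, with a median of -0.09 at the percentile 0.41, led by the succinate dehydrogenase gene Sdha at -0.90, Ndufv2 at -0.47 and Uqcrc2 at -0.46. Markers of conventional type 1 dendritic cells were lower beside both groups, in 6 of 10 cases with 1 higher and a median of -0.22 at the percentile 0.87, among them Itgae at -0.49, Gcsam at -0.45 and Naaa at -0.38. The 6 T and NK cell markers above background had a median of -0.13, inside the central 95%, and a mean of -0.26 at the percentile 2.40, with Il2rb at -0.84 and Cd5 at -0.45. The median was -0.06 for 11 conventional type 2 dendritic cell markers, 0 for 18 monocyte and macrophage markers and 0.06 for 5 B cell markers, all inside the central 95%. Exonic control probe sets were lower in this array by a mean of -0.13 and intronic ones higher by 0.15, and after centring on the median the cell cycle median was -0.05 and the oxidative phosphorylation median -0.04.

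Interferon-stimulated genes were lower in 31 of 46 cases and higher in 5 with oxymatrine, with a median of -0.07 at the percentile 1.56. The members went apart, with Parp9 at -0.58 and Ifit2 at -0.23 against Oasl2 at 0.49 and Mx2 at 0.44. Microtubule and polarity genes had a median of -0.09 with 16 of 26 lower, although Pard6a, a polarity protein, was higher by 0.99 and Tubg1 differed by -0.60. Glucocorticoid response genes had a median of -0.11 with 10 of 16 lower, among them Errfi1 at -0.48 and Fkbp5 at -0.41, while the metallothionein gene Mt2 was higher by 0.47. After centring on the median, the medians of the interferon, microtubule and glucocorticoid lists were -0.02, -0.04 and -0.06. By their means, these 3 lists lay at the percentiles 20.9, 29.4 and 17.4, inside the central 95%. The microtubule list was also inside with all measured members and with no level filter, and the glucocorticoid list with the 99th percentile filter. Again 6 of 31 lists were outside the central 95%, where lists of unrelated genes would give 1.55, which does not measure chance for these lists. With random lists drawn from the listed genes, the cell cycle list and the type 1 dendritic cell list stayed outside, at the percentiles 1.77 and 2.25. The oxidative phosphorylation list then lay inside, at 2.79.

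The medians of the other lists placed lay inside the central 95% in both comparisons with control. Among all lists, some whose median lay inside in a comparison had a mean outside it: with astragaloside IV those of cholesterol synthesis genes (percentile 0.73), cell cycle genes (0.74), T and NK cell markers (1.74) and maturation genes (2.18), and with oxymatrine those of ribosomal protein (0.04), housekeeping (0.15), chemoattractant receptor (0.87) and oxidative stress genes (0.93) lay low. The ribosomal protein and housekeeping lists are not separate here, as both had Rplp0 as their lowest member with oxymatrine, at -0.92. Dendritic cell maturation genes had medians of 0 and -0.01, and inflammatory cytokines 0 and -0.01, for astragaloside IV and oxymatrine in turn, and those of NF-kB and immediate early genes rounded to 0 in both. Within them, Marcksl1 differed by -0.60 and -0.81, Il1a by -0.67 and -0.51, and Tnf by -0.35 and -0.25. Tnip1, a restraint on NF-kB, differed by 0.01 with astragaloside IV and -0.73 with oxymatrine. Medians were -0.04 and -0.05 for heat shock genes, -0.02 and -0.01 for cholesterol synthesis genes, -0.01 and -0.03 for glycolysis and hypoxia genes, 0 and 0 for p53 targets, -0.07 and -0.11 for aryl hydrocarbon receptor targets and -0.03 and -0.02 for housekeeping genes. In the cholesterol pathway Mvk differed by -0.47 and -0.93 and Dhcr7 by -0.32 and -0.66, and in glycolysis Pgam1 by -0.64 and -0.58 and the glucose transporter gene Slc2a3 by -0.51 and -0.69. Erythroid and mast cell lists had 2 and 3 members above background, too few to be placed, among them Car2 at -0.42 and -0.11 and Kit at -0.01 and -0.13.

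**Figure D2:**
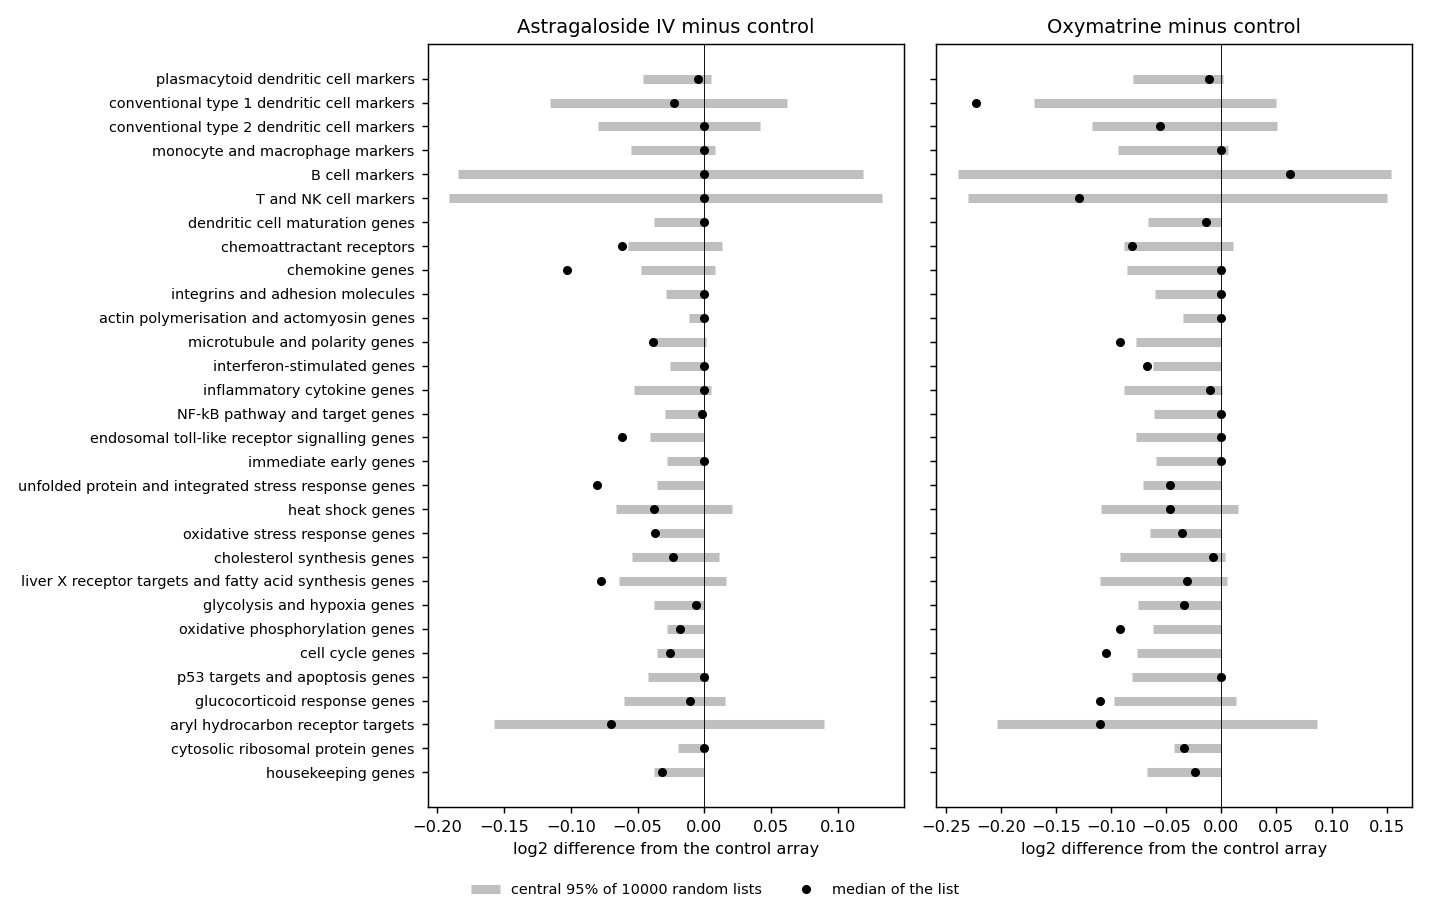
Median log2 difference of each gene list (points) from the control array for astragaloside IV (left) and oxymatrine (right), with grey bars for the central 95% of medians of 10000 random lists matched on size and level. In each panel 6 points lie outside their bar, all to the left, with chemokine genes at -0.10 for astragaloside IV and conventional type 1 dendritic cell markers at -0.22 for oxymatrine.

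Set against each other, the treated arrays differed in few genes. Zfp763 was higher with astragaloside IV than with oxymatrine by 1.52, Zfp976 by 1.34 and Zfp365 by 1.22, followed by Polr2l, a subunit shared by RNA polymerases, with 1.09, Trim30d with 1.08 and Thap11 with 1.05. Lower with astragaloside IV were Tph2 with -1.61, Wfdc9 with -1.41, Myo9a with -1.31, Skint10 with -1.22, Npl with -1.16 and Angptl6 with -1.05. In Tph2, Skint10, Npl and Angptl6 the astragaloside IV value, and in Zfp763 the oxymatrine value, lay below background. In all, 17 of 10671 genes, or 0.159%, were 2-fold apart, 9 higher and 8 lower with astragaloside IV, and 7 higher and 10 lower after centring on the median. With no level filter 35 were higher and 47 lower. Of the receptor genes, 22, or 1.56% (95% exact binomial interval 0.980 to 2.35%), were as far apart.

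Ribosomal protein genes were slightly higher with astragaloside IV than with oxymatrine, in 24 of 35 cases with 2 lower, a median of 0.04, or 0.02 after centring on the median, and a percentile of 99.9. Rplp0 was the widest apart, by 0.76, and Rps9 and Rps14 followed with 0.24 and 0.18. Against control, this list had a median of 0 with astragaloside IV and -0.03 with oxymatrine, the latter becoming 0.02 after centring on the median. Interferon-stimulated genes were higher with astragaloside IV in 28 of 46 cases and lower in 8, with a median of 0.03 at the percentile 97.8, and Ifit2 differed by 0.53. That median became 0.00 after centring on the median, and it lay inside the central 95% with the 99th percentile filter. Chemokine genes were lower in 14 of 21 cases with a median of -0.03 at the percentile 1.06, and the liver X receptor list had a median of -0.02 at the percentile 1.61. Their medians were both -0.05 after centring on the median. By their means both lay inside. The liver X receptor list was also inside with the 99th percentile filter and, at the percentile 4.27, with random lists drawn from the listed genes. These 4 lists were outside the central 95%. Exonic control probe sets were also higher with astragaloside IV than with oxymatrine, in 58.6% of cases, by a mean of 0.09 and a median of 0.055. Both values exceed the ribosomal and interferon medians.

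Both treated arrays shared 5 genes that were 2-fold from control in the same direction. Ypel1, of the yippee-like family, was higher by 1.04 with astragaloside IV and 1.08 with oxymatrine. Abl1 differed by -1.21 in both, Hvcn1 by -1.03 and -1.15, Scd3 by -1.07 and -1.23, and Xcl1 by -1.63 and -1.12. Abl1, Scd3 and Xcl1 lay below background in at least 1 treated array. None was 2-fold from control in opposite directions. Independent lists of these sizes would share 0.00525 genes on the higher and 0.0255 on the lower side, but both differences use the same control array, and shuffling each gene's values among the arrays gave 4.23 shared genes on average (0 to 9 in 100 shuffles). The observed 5 lay within the shuffled range. The shuffles keep each gene's observed values, and with them any effect in the treated arrays. They therefore cannot show how many shared genes a shared control array alone would give.

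Across the 10671 genes, which are not independent replicates, the differences of the treated arrays from control had a Pearson's r of 0.538 and a Spearman's rho of 0.512. Shuffled arrays gave a mean r of 0.50 (0.470 to 0.523) and a mean rho of 0.451. The covariance was 0.0245, against 0.0229 in the shuffled arrays (0.0211 to 0.0243), a difference of 0.00165. Split by array through the covariances of the differences, the SD was 0.16 for control, 0.12 for astragaloside IV and 0.17 for oxymatrine. These values hold noise and effects together. The value for control is the square root of the covariance above, so it also holds any effect common to the treated arrays.

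**Figure D3:**
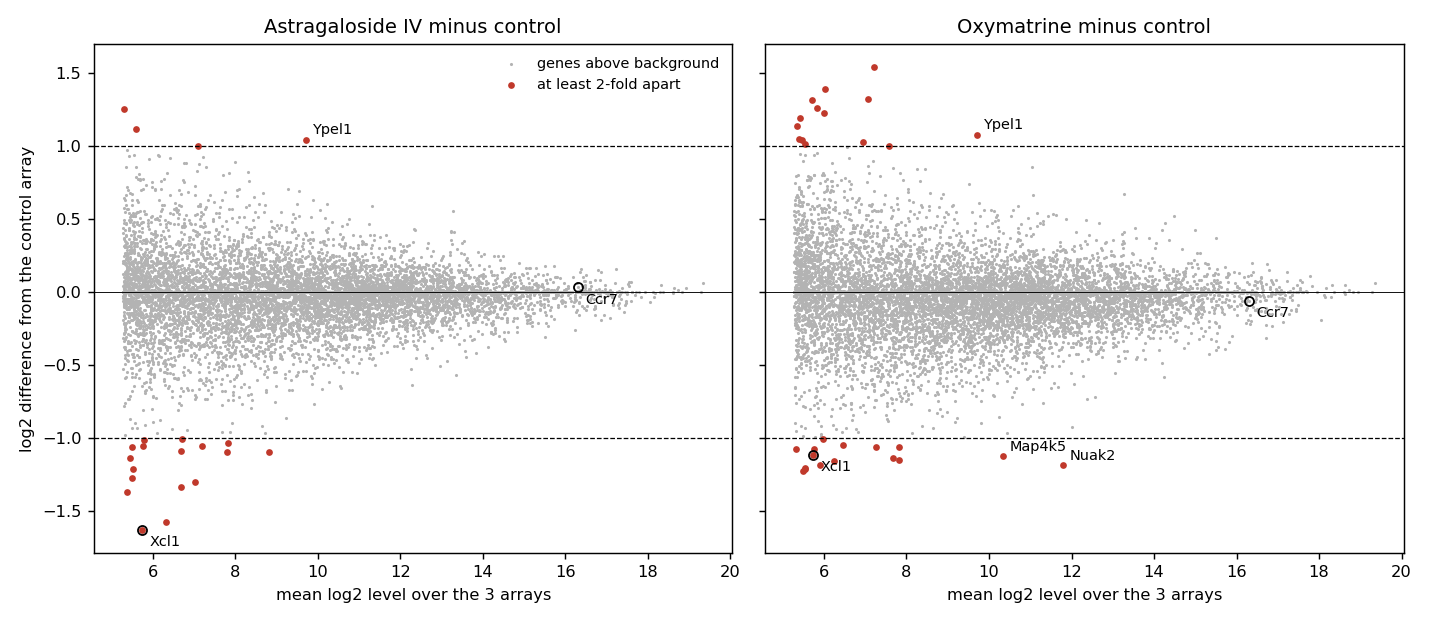
Log2 difference from the control array against the mean log2 level over the 3 arrays for the 10671 genes above background, for astragaloside IV (left) and oxymatrine (right), with genes at least 2-fold apart in red and dashed lines at 2-fold. Of the red points, 1 of 21 on the left and 3 of 30 on the right lie at a level of 9 or more, and the spread narrows as the level rises.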

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

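The tests of the intronic pattern were chosen after the result was seen. Control probe sets that lie in introns of housekeeping genes, by the naming convention of the array, take no part in the comparisons of genes, and they were higher in both treated arrays. Over 5222 such probe sets the mean difference from control was 0.16 with astragaloside IV and 0.15 with oxymatrine, 57.4% and 57.2% of them being higher, while the treated arrays differed from each other by 0.01. Over 1324 exonic control probe sets the means were -0.04 and -0.13. Without background subtraction, a uniform rise in background would be at least as large in dim probe sets on the log2 scale. The rise in the brightest eighth, at levels of 7.73 to 18.8, exceeded that in the dimmest by 0.22 (SE 0.05 over probe sets), at 0.30 against 0.08. Between them it was uneven, with 0.20 in eighth 6 and 0.15 in eighth 7. RMA subtracts background and equalises the arrays by quantiles, so these values cannot exclude a rise in background. Genomic DNA in the treated samples may also account for the intronic rise. Receptor genes were higher by 0.262 of the rise of intronic controls of the same level in log2 units. In units of each set's SD this share was 0.740. Genomic DNA cannot be told apart from more unspliced RNA in the treated cells, which was not tested. With 1 array per group, unspliced RNA cannot be separated from how a sample was prepared.

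A set of 10 genes, among the 17 that were 2-fold apart between the treated arrays, lay on opposite sides of control. Predicted genes, numbered clones, receptor genes and small RNAs were left out of this set, though the 17 include them. The difference was not tested because each group has 1 array. Genes picked for a wide gap between the treated arrays can have the control value inside that gap through this choice alone. How often this would happen without any effect was not computed, so opposite effects of the compounds cannot be read from these genes. Astragaloside IV minus oxymatrine was 1.52 for Zfp763, 1.34 for Zfp976, 1.22 for Zfp365, 1.09 for Polr2l, 1.08 for Trim30d and 1.05 for Thap11. It was -1.61 for Tph2, -1.22 for Skint10, -1.16 for Npl and -1.03 for Tex43, the last named only because it met this rule. With astragaloside IV, Thap11, Trim30d and Tex43 differed from control by 0.09, 0.11 and -0.90, and with oxymatrine by -0.96, -0.97 and 0.13, so that 1 side lay near control. For Zfp763, Tph2, Skint10, Npl and Tex43 the lower of the treated values was below background. Groups of 1 array allowed no search for outlying samples.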

How the results depend on the processing

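No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The random lists drawn from the listed genes were chosen after seeing the data. So was the stricter match of listed symbols, on which the main list values rest, and the looser first match was kept as an alternative. Of the values for single genes and lists under the alternatives, 4693 stayed within the spread at their level or of random lists and 254 moved beyond it. Many stayed by construction, since level filters leave a gene's difference as it is and averaging over probe sets alters only genes with several. Median centring shifts every gene by at most 0.051. No list outside the central 95% and no named 2-fold gene changed direction, but a 2-fold gene could hardly have done so. The counts of 2-fold genes depended on the threshold and the level filter. For astragaloside IV against control (21) they were 227 at 1.5-fold, 1 at 3-fold, 79 with no level filter and 11 with the 99th percentile filter. For oxymatrine against control (30) they were 353, 0, 90 and 17 in the same order, and between the treated arrays (17) 275, 1, 82 and 9. The shared genes (5) were 99, 0, 19 and 2, and 8 with the filter on the highest array. Centring on the median, quantile normalisation, lowess centring and averaging over probe sets kept every count within 1.5 times, with at least 26 of the 30 oxymatrine genes and 19 of the 21 astragaloside IV genes shared. The split for oxymatrine moved from 14 higher and 16 lower to 10 and 24 after quantile normalisation, and that between the treated arrays from 9 and 8 to 7 and 10 after median centring. With no level filter the splits were 42 and 37 for astragaloside IV (4 and 17), 57 and 33 for oxymatrine, 35 and 47 between the treated arrays and 10 and 9 for the shared genes (1 and 4). The correlation of the differences was 0.520 with no level filter. Lists outside the central 95% numbered 2 instead of 6 for each compound against control with random lists from the listed genes, and 2 instead of 4 between the treated arrays with the 99th percentile filter. Median centring moved 79 values, lowess centring 47 and quantile normalisation 46. Taking the list mean moved 67 of 93 list values, put 8 lists outside for each compound against control, all low, and between the treated arrays turned 2 higher and 2 lower lists into 4 higher and 0 lower. Stricter thresholds and filters count fewer genes by construction; the cause of the other shifts was not tested. Dim genes limit what can be read: the SD of the difference was 0.33 among receptor genes and 0.08 among ribosomal protein genes for astragaloside IV, 0.32 and 0.18 for oxymatrine, and 0.33 and 0.14 between the treated arrays.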

Other observations

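Ranked by the difference relative to the spread of genes of the same level, a ranking chosen after the data had been seen, brighter genes came forward among those lower with oxymatrine. The 12 lowest then had a median level of 10.9, and 3 of them were also among the 12 lowest by size. The 12 highest with oxymatrine had a median level of 7.01 and shared 9, and the 12 highest and 12 lowest with astragaloside IV, at 8.07 and 8.27, shared 8 and 7. The lower genes with oxymatrine included the ribosomal stalk gene Rplp0 by a difference of -0.92, the ectonucleotidase gene Entpd1 (CD39) by -0.99, Fbxo6 by -0.97, Tnip1 by -0.73, the membrane-binding Bin2 by -0.72 and the proteasome subunit gene Psma3 by -0.58. Cracr2b, a regulator of calcium entry, was higher by 0.85. In the astragaloside IV array the checkpoint gene Vsir (VISTA) differed by -0.57, Pgam1 by -0.64, Cd5l by -0.97 and Fkbp1b by -1.10. Trmt112, a partner of methyltransferases, was higher in both, by 0.55 with astragaloside IV and 0.67 with oxymatrine.

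Of 18 measured genes of type I and III interferons, 3 were above background. Ifna5 was at 7.03 in control, 7.03 with astragaloside IV and 7.59 with oxymatrine, Ifnb1 at 5.74, 5.74 and 6.31, and Ifnl3 at 6.10, 6.22 and 6.16.

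The tests of the following patterns were chosen after the results were seen. The differences of the treated arrays from control were correlated across genes. The r of 0.538 lay above the highest of 100 shuffles, 0.523. The shuffles were meant to stand for a shared control array with equal noise in all 3 arrays. They keep each gene's observed values, and with them any effect in the treated arrays. They also treat each gene on its own and do not cover noise that moves many genes together. They therefore cannot settle whether equal noise would give the whole of the correlation. A noisier control array may add to r. Over the 1410 receptor genes r was 0.499 (SE 0.026), below that of the main set by less than 2 SE. Of these genes 71 lay above background, as every gene of the main set did, so the values of r come from unlike levels. A noisier control array and an effect common to the treated cells cannot be told apart with 1 control array. That common effect, of the compounds or of CCL21, was not tested.

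Dim genes made up most of the 2-fold differences from control. Array noise at low signal is a candidate explanation that these arrays cannot settle. Other genes above background, weighted to the levels of the receptor genes above background, passed 2-fold in 0.850% of cases with astragaloside IV and 1.10% with oxymatrine, and of those 71 receptor genes 0 did, which allows a share of up to 5.06% by the exact binomial interval. The receptor genes reach a level of 7.45 and say nothing of brighter ones, where 4 genes with astragaloside IV (Fkbp1b, Hvcn1, Kbtbd7 and Ypel1) and 7 with oxymatrine (Faap20, Hvcn1, Map4k5, Nkiras1, Nuak2, Socs3 and Ypel1) were 2-fold apart. Nkiras1 and Socs3 were named after their values were seen, and effects of the compounds on these genes remain untested.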
